A study of Mus musculus with 10 samples.

How the data were processed

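RNA was extracted with RNeasy from cardiac myocytes isolated from the left ventricle of adult C57BL/6 mice and sequenced as stranded paired-end libraries on an Illumina HiSeq instrument, per the labels. The labels give polyA RNA as the molecule, while the protocol text describes removal of ribosomal RNA with Ribo-Zero, and the selection of RNA is thus uncertain. The labels define 3 groups: control (3 libraries), CTCF knockout (4 libraries) and TAC, transverse aortic constriction (3 libraries). The genotype of the TAC mice is not given. Each library carries a mouse number of its own and was treated as an independent replicate.

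The deposited transcript files give, for each of 109869 annotated transcripts, an FPKM value that the authors made with Cufflinks, normalized for transcript length and library size. A second column holds the Cufflinks score of each transcript, which as deposited is a whole number that ranks a transcript against the most abundant isoform of its gene, and this score was not used. The submitters' processing notes name TopHat2 2.1.0, Bowtie2, Cufflinks 2.2.1, Cuffdiff and the mouse genome build mm10. The files hold no read counts, so the number of reads per library is unknown and no counting error was computed. The median coverage listed per FPKM, which scales with depth, ranged from 3.90 to 6.09 between libraries.

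Transcript FPKM was summed by gene ID, which gave 45882 gene IDs, 930 of them without a symbol. Gene types came from GENCODE annotation of the GRCm38 assembly. A set of 22 gene IDs was set apart because each was listed at 0 in some libraries and at 100 FPKM or more (median of the libraries above 0) in others, a sign of loci that were not quantified. This rule was set after these values were seen and before any test. It removed 6 gene IDs of at least 300 nt, namely Ttn, mt-Atp6, mt-Co3, Rn7s1, Rn7s2 and Gm28437. Another 7781 gene IDs with a longest transcript under 300 nt were left out, because FPKM of short transcripts is unstable, and 38095 remained. Libraries were rescaled by the median of ratios to the geometric mean, with factors from 0.912 to 1.10, and genes with a mean rescaled FPKM of at least 1 were tested (11358 gene IDs, 10327 of them protein-coding). The values printed in FPKM are rescaled.

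Levels were compared as log2(FPKM + 1) in a linear model of all 10 libraries with limma 3.58.1 in R 4.3.3, with moderated statistics and a trend of the variance with the mean. The comparisons were CTCF knockout with control, TAC with control and CTCF knockout with TAC. P values were two-sided and adjusted over all tested genes by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Rose and fell are used of called genes. Tools for read counts were not used, since the values are not counts.

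Lists of marker and pathway genes were fixed before the data were examined, as were the comparisons, filters, fixed panel and most alternatives. The 40 lists were fetal and hypertrophic stress genes, mature sarcomere, calcium handling, ion channels and connexins, intercalated disc, fatty acid oxidation, nuclear encoded oxidative phosphorylation, mitochondrially encoded genes, tricarboxylic acid cycle, glycolysis and glucose uptake, mitochondrial biogenesis regulators, cardiac transcription factors, extracellular matrix and fibrosis, and markers of fibroblasts, endothelial cells, macrophages and leukocytes, lymphocytes, smooth muscle and pericytes, Schwann cells and nerve, epicardium and adipocytes, erythroid cells and atrium. Further lists were cell cycle, p53 targets, integrated stress response, endoplasmic reticulum chaperones, heat shock proteins, interferon response, NF-kB and cytokine genes, immediate early genes, NRF2 targets, muscle atrophy and autophagy, hypoxia response, circadian clock, cohesin and chromatin architecture, imprinted genes, clustered protocadherins, Hox genes, cytoplasmic ribosomal proteins and sex-linked genes. They held 863 entries, of which 676 were tested, and 32 symbols had no gene in the files. Col1a1 and Col1a2 are in both the matrix and the fibroblast list. Lists with at least 5 tested genes, 37 in all, were tested with camera of limma at its preset correlation of 0.01 between genes, and p values were adjusted over lists. This competitive test asks whether a list ranks above or below the other genes, and its preset correlation gives small p values where genes of a list move together for any reason. The same test with a correlation estimated from the data, and fry, were run as alternatives. Within each list, p values were also adjusted over the list alone.

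Genes were named by a fixed rule. It covered Ctcf, the fixed panel of heart failure genes, the 10 highest and 10 lowest fold changes of each comparison with control and the 5 highest and 5 lowest between knockout and TAC, up to 4 members of each list by adjusted p, and members needed to state a small count. The highest and lowest genes had to be called, with group values that do not overlap, and genes with numbered placeholder names, pseudogenes and mitochondrially encoded genes were left aside. Sequence similarity of the genes that set knockout and TAC apart was searched with blastn 2.17.0 for matches of at least 95% identity over at least 100 nt.

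The overlap of both responses and the correlation of their fold changes were set against 100 simulated data sets of unchanged groups that share the same controls. Neighbouring tested genes that do not overlap were compared by Spearman correlation of their fold changes, with 1000 shuffles of gene order and a one-sided permutation p. The model was tested on simulated data with 11358 genes, 200 of them changed. Changes of 1 on the log2 scale were recovered for 93, 91 and 94 of 100 genes in the 3 comparisons and changes of 2 for 100 of 100 in each, with 9, 9 and 3 unchanged genes called. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

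Alternatives changed 1 choice at a time: no rescaling, quantile normalization, a pseudocount of 0.1 or 5, no filter on the mean, a mean of at least 5, no length filter, no mitochondrially encoded genes, robust or untrended moderation, weights per library, a fit of the 2 groups compared, a block by replicate number, a term for sex, and each library left out in turn. For neighbours, pairs within 50 kb and pairs on opposite strands were tried. After the data were examined, 4 alternatives were added: genes listed at 0 kept, the level of Arntl as a covariate, the immediate early gene score as a covariate, and protein-coding genes alone.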

Results

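RNA of isolated adult cardiac myocytes from the left ventricle of C57BL/6 mice was sequenced in 10 libraries, each labelled with a mouse of its own. Of these libraries, 3 came from control mice, 4 from CTCF knockout mice and 3 from mice after transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle with pressure. The series describes the TAC mice as having diseased hearts, and their genotype is not labelled. CTCF is a zinc finger protein that binds DNA and takes part in forming chromatin loops and domains. Each library listed an FPKM (a level corrected for transcript length and library size) for 109869 transcripts of 45882 gene IDs, and 58663 to 64693 transcripts lay above 0. Transcript FPKM summed to between 582496 and 823272 per library. The files hold no read counts, so the depth of each library is unknown. The coverage listed per FPKM, a relative measure of depth, had medians from 3.90 to 6.09, a 1.56-fold range. Across genes, log2 levels of libraries of the same group correlated with Pearson r from 0.971 to 0.988, and those of different groups with r from 0.942 to 0.980, where genes are not independent replicates. The largest principal component held 39.4% of the variance and placed the 3 control libraries (-35.8 to -25.0) apart from the other 7 (7.06 to 16.5). Xist and Y-linked genes marked 6 mice as female and 4 as male. The males were control replicate 2, knockout replicate 4 and TAC replicates 1 and 3, so sex was not balanced between the groups.

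Ctcf, the targeted gene (ENSMUSG00000005698, chromosome 8, 105636568 to 105682922, plus strand, mm10), was measured in every library as a check of the labels. Its level was 8.81, 8.34 and 6.80 FPKM in the control libraries and 2.90, 4.01, 2.60 and 4.42 FPKM in the knockout libraries. The means were 7.99 ± 1.05 (SD, n = 3) and 3.48 ± 0.872 FPKM (SD, n = 4), so the knockout libraries held 43.6% of the control mean, and all 4 lay below all 3 controls. The log2 fold change was -1.02 (limma, adjusted p = 0.00136). The TAC libraries lay at 7.32, 5.70 and 5.22 FPKM, with a mean of 6.08 ± 1.10 FPKM (SD, n = 3) and a log2 fold change against control of -0.35 (limma, adjusted p = 0.201). Fold changes here and elsewhere are on the log2(FPKM + 1) scale, which understates the change of genes with low levels.

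The comparison of CTCF knockout with control libraries asks which transcripts differ in isolated cardiac myocytes of knockout mice, whose Ctcf RNA lay at 43.6% of the control mean. The natriuretic peptide genes Nppa and Nppb and the strain-induced Ankrd1 rose in the knockout, and Ces1d and the calcium cycling genes Ryr2, Pln and Atp2a2 fell. Nppa, which encodes atrial natriuretic peptide (ENSMUSG00000041616, chromosome 4, 148000722 to 148002079, plus strand), rose from 43.7 ± 0.323 FPKM (SD, n = 3) to 1363 ± 341 FPKM (SD, n = 4). Its log2 fold change was 4.90 (adjusted p = 1.55e-06). Ankrd1, a nuclear and sarcomeric ankyrin repeat protein induced by strain (ENSMUSG00000024803, chromosome 19, 36111965 to 36119844, minus strand), rose from 257 ± 99.3 (SD, n = 3) to 2805 ± 170 FPKM (SD, n = 4). Ces1d, a carboxylesterase that breaks down lipids (ENSMUSG00000056973, chromosome 8, 93166068 to 93197838, minus strand), fell from 104 ± 29.4 (SD, n = 3) to 5.62 ± 2.73 FPKM (SD, n = 4), a log2 fold change of -4.07 (adjusted p = 2.94e-05). Nppa is overlapped on the other strand by Gm13054, which rose with a log2 fold change of 4.92, and the division of reads within this pair is uncertain.

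Most other genes of the fixed panel of heart failure genes changed as well. Nppb, which encodes brain natriuretic peptide, rose from 163 ± 111 (SD, n = 3) to 679 ± 156 FPKM (SD, n = 4), with a log2 fold change of 2.27 (adjusted p = 0.00327). Myh7, the slow myosin heavy chain of the fetal mouse ventricle, rose from 194 ± 76.8 to 751 ± 163 FPKM (log2 fold change 2.02, adjusted p = 0.00248). Ryr2, the calcium release channel of the sarcoplasmic reticulum, fell from 218 ± 79.1 to 94.6 ± 24.5 FPKM (log2 fold change -1.18, adjusted p = 0.00799). Pln, which restrains the calcium pump, fell by 0.68 on the log2 scale, and Atp2a2, the pump itself, by 0.73. Myh6, the main myosin heavy chain of the adult mouse ventricle, fell by 0.53 on the log2 scale (adjusted p = 0.0298). For all 8 of these panel genes, the 4 knockout libraries lay on one side of the 3 controls. The Myh6 call was lost in 10 of 28 alternatives, among them those without control replicate 1 or 3 or without knockout replicate 1, 2 or 4, with adjusted p from 0.00134 to 0.303 over all of them. The call of Atp2a2 was lost with quantile normalization and with no filter on the mean (adjusted p from 0.00229 to 0.165). In the panel, 1 further gene was not analysed here.

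**Figure D1:**
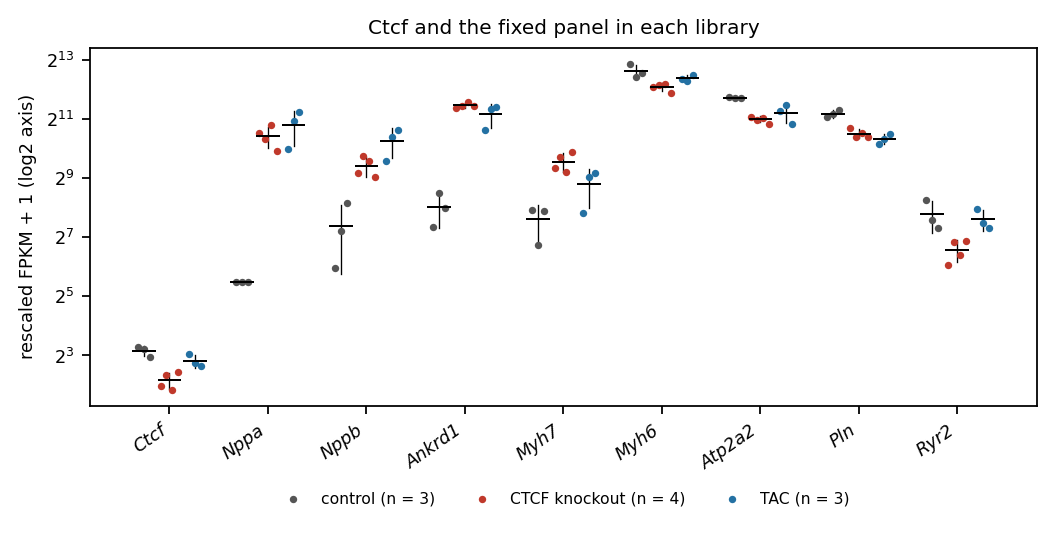
Levels of Ctcf and the fixed panel genes in each library, as rescaled FPKM + 1 on a log2 axis, with points for libraries, horizontal lines for group means and vertical bars for the SD (3 control, 4 CTCF knockout and 3 TAC libraries). Nppa lay at a mean of 43.7 FPKM in control, 1363 FPKM in knockout and 1786 FPKM in TAC libraries, while Ctcf lay at 7.99, 3.48 and 6.08 FPKM.

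Beyond Nppa and Ankrd1, the highest fold changes of the named-gene rule belonged to Mnd1, Uchl1, Cilp, Postn, Fam198b, Lockd, Ube2c and Comp. Mnd1, a partner of the recombinases of meiosis (ENSMUSG00000033752, chromosome 3, 84087933 to 84155786, minus strand), rose from 0.640 ± 0.327 (SD, n = 3) to 12.5 ± 3.03 FPKM (SD, n = 4; log2 fold change 3.03, adjusted p = 3.24e-06). Uchl1, a deubiquitinating enzyme abundant in neurons, rose from 5.34 ± 0.877 to 42.3 ± 3.93 FPKM (log2 fold change 2.78). The matrix proteins Cilp, Postn and Comp rose with log2 fold changes of 2.73, 2.67 and 2.28, and Fam198b with 2.44. Ube2c, a ubiquitin-conjugating enzyme of mitosis, rose from 0.139 ± 0.0871 to 5.37 ± 4.25 FPKM, with knockout replicate 4 at 11.7 FPKM and the other knockouts between 2.95 and 3.59 FPKM. The long noncoding RNA Lockd was listed at 0 in all 3 controls and at 2.77, 4.41, 1.65 and 11.7 FPKM in the knockouts, and it shares stretches of up to 163 nt with 219 other genes, so its level is uncertain. After Ces1d, the lowest were Alb, Phkg1, Abhd1, Pfkfb1, Kcnv2, Lgals4, Pdzd9, Pla2g5 and Acot1. Albumin, Alb, is a secreted product of the liver and lay at 3.80, 4.15 and 3.49 FPKM in the controls, and in the knockouts it was listed at 0 in replicates 1 to 3 and at 0.0219 FPKM in replicate 4. Of 57 liver transcripts above 0 in some library, 31 lay higher in all 3 controls than in all 7 other libraries, in step with Alb. The muscle glycogen enzyme subunit Phkg1 and the glycolysis regulator Pfkfb1 fell by 2.08 and 2.06 on the log2 scale, the potassium channel subunit Kcnv2 by 1.91, and the acyl-CoA thioesterase Acot1 by 1.83, where reads of its close copy Acot2 make the level uncertain. The hydrolase Abhd1, the galectin Lgals4, Pdzd9 and the secreted phospholipase Pla2g5 fell by 2.06, 1.89, 1.87 and 1.86.

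Among the lists of stress, contraction, calcium, channel and disc genes, the stress genes stood highest and the channel and calcium genes lowest by median. Of 13 tested stress genes, 11 rose, 1 fell and 1 did not pass (12 and 1 passed adjusted over the list alone), with a median log2 fold change of 1.13. The actin cross-linker partner Xirp2 rose by 1.13 on the log2 scale to 211 ± 24.2 FPKM, and Acta2, smooth muscle actin, was the gene that fell, by 1.39. The list test, camera, gave an adjusted p = 4.22e-08, and adjusted p = 0.228 with an estimated correlation. Of 19 mature sarcomere genes, Mybpc3, Actn2 and Myom2 rose, Myh6 and Tnni3 fell and 14 did not pass (3 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.197). Calcium handling genes fell in 7 of 17 cases and 10 did not pass (7 fell and 1 rose adjusted over the list alone), with a median of -0.35. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell by 1.09, the calcium channel subunit Cacna2d1 by 0.98 and triadin, Trdn, by 0.68. For this list camera gave an adjusted p = 0.0092 (adjusted p = 0.228 with an estimated correlation), and the call was lost with quantile normalization (adjusted p = 0.0749, range over alternatives 0.000156 to 0.228). Ion channels and connexins fell in 12 of 21 cases and 7 did not pass (14 fell adjusted over the list alone). The potassium channels Kcnj3 and Kcnd2 fell by 1.61 and 1.60, and Kcnj11 rose. The median of -0.45 gave an adjusted p = 4.78e-05, and adjusted p = 0.239 with an estimated correlation, and the call was lost among genes of mean FPKM at least 5 (adjusted p = 0.0521, range 1.36e-06 to 0.239). In the intercalated disc list of 15 genes, Pkp2, Ctnnb1 and Xirp2 rose, Dsg2 and Dsc2 fell and 10 did not pass (3 and 2 adjusted over the list alone), with no call (adjusted p = 0.577).

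Most fatty acid oxidation genes fell, while in the other lists of energy metabolism most genes did not pass. Of 27 fatty acid oxidation genes, 21 fell, none rose and 6 did not pass (23 fell adjusted over the list alone), with a median log2 fold change of -0.65. Acaa2, a thiolase of the mitochondrial beta-oxidation spiral, fell from 429 ± 47.6 to 169 ± 26.8 FPKM, Hadh fell by 0.89 and Decr1 by 0.90. The list was called by camera (adjusted p = 2.09e-12; adjusted p = 0.282 with an estimated correlation). Tricarboxylic acid cycle genes held 4 that fell among 16 (Idh3a, Dld, Suclg2 and Pdha1) and 12 that did not pass (4 fell adjusted over the list alone), with a median of -0.23, an adjusted p = 0.00694 and adjusted p = 0.814 with an estimated correlation. Of 72 nuclear genes of oxidative phosphorylation, Ndufs1, Cox7a1, Atp5f1 and Atp5j fell and 68 did not pass (0 passed adjusted over the list alone, in limma), with a median of -0.11. This call (adjusted p = 0.0262; adjusted p = 0.944 with an estimated correlation) was lost in 9 of 29 alternatives, among them those without control replicate 2 (0.367), control replicate 3 (0.0974) or knockout replicate 4 (0.609), and with no rescaling its mean turned to 0.01 (0.0958, range 7.75e-05 to 0.944). Of 8 mitochondrially encoded genes, mt-Nd2 and mt-Nd3 fell and 6 did not pass (2 fell adjusted over the list alone), with a median of -0.34. The call (adjusted p = 0.0337, and 0.814 with an estimated correlation) was lost in 9 of 28 alternatives. The adjusted p rose to 0.0974 without control replicate 3, to 0.118 and 0.0774 without knockout replicate 1 or 3, and to 0.796 with quantile normalization (range 0.00947 to 0.814). Glycolysis genes went both ways: Hk1, Gpi1, Pfkp, Pgk1 and Eno1 rose, Slc2a4 and Ldhb fell and 12 of 19 did not pass (8 and 3 adjusted over the list alone), without a call for the list (adjusted p = 0.0609). Pfkp, the platelet form of phosphofructokinase, rose by 1.61 on the log2 scale to 49.1 ± 10.9 FPKM, while Slc2a4, the insulin-responsive glucose transporter, fell by 0.61. Among 16 regulators of mitochondrial biogenesis, Ppara, Rxra and Twnk fell and 13 did not pass (3 fell adjusted over the list alone; adjusted p = 0.0633 for the list).

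Extracellular matrix genes formed the list with the smallest p, and fewer of the markers of other cell types passed. The calls of the matrix, fibroblast and macrophage lists were lost with an estimated correlation, and those of the 2 marker lists with fry as well (0.123 and 0.196). Markers of other cell types were measured in the same libraries, so the levels of matrix genes cannot be assigned to the myocytes. Of 26 matrix and fibrosis genes, 23 rose and 3 did not pass (23 adjusted over the list alone), with a median log2 fold change of 1.29. The collagens Col8a1, Col1a1 and Col1a2 rose by 1.74, 1.61 and 1.41, with Col1a1 at 2.31 ± 0.720 FPKM in control and 9.03 ± 1.70 FPKM in knockout libraries. Camera gave an adjusted p = 2.41e-22, and adjusted p = 0.173 with an estimated correlation. Fibroblast markers rose in 7 of 15 cases and 8 did not pass (7 adjusted over the list alone), with Mfap5 from 4.64 ± 2.06 to 14.8 ± 4.03 FPKM and a median of 0.24. Their call (adjusted p = 0.0131; adjusted p = 0.814 with an estimated correlation) was lost in 4 of 29 alternatives, among them that without control replicate 2 (0.242, range 0.000651 to 0.814). Macrophage and leukocyte markers Adgre1, Ctss and Coro1a rose, the scavenger receptor Cd163 fell and 13 of 17 did not pass (4 and 1 adjusted over the list alone), with a median of 0.36. This list (adjusted p = 0.0084; adjusted p = 0.814 with an estimated correlation) was not called in 4 of 29 alternatives, among them that without control replicate 1 (0.069, range 0.000209 to 0.814). No call was made for endothelial markers (Emcn, Vwf and Eng rose, Aqp1 fell, 13 of 17 did not pass, 3 and 1 adjusted over the list alone; adjusted p = 0.198). Smooth muscle and pericyte markers had no call either (Cspg4 rose, Acta2 fell, 9 of 11 did not pass, 1 and 1 adjusted over the list alone; adjusted p = 0.938). Among 5 epicardial and adipocyte and 5 erythroid markers, limma called 0 at any adjustment (adjusted p = 0.925 and 0.154 for the lists), with medians of 0.13 and -0.96. Of 6 atrial markers, Dkk3 and Nppa rose, Kcnj3 and Tbx5 fell and 2 did not pass (2 and 2 adjusted over the list alone), and the median of -0.12 stood against a mean of 0.58 and an upward test (adjusted p = 0.938). Lymphocyte and Schwann cell lists each had 1 tested gene, with log2 fold changes of 0.08 and 0.00, and were too small for the test.

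Among stress and signalling lists, cell cycle genes, the integrated stress response, interferon response genes and p53 targets stood higher in the knockout and endoplasmic reticulum chaperones lower. Of 15 cell cycle genes, 9 rose and 6 did not pass (11 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.92. Cdk1, the kinase that drives entry into mitosis, rose from 0.328 ± 0.0457 to 4.68 ± 3.89 FPKM, and Top2a and Rrm2 rose by 1.70 and 1.69, with the mean log2 score of the list at 2.72 in knockout replicate 4 and between 1.61 and 1.73 in the other knockouts. The list was called (adjusted p = 0.000198; adjusted p = 0.725 with an estimated correlation). Integrated stress response genes rose in 7 of 14 cases and 7 did not pass (8 adjusted over the list alone), with Aldh18a1, an enzyme of proline synthesis, up by 1.24 and the transcription factor Ddit3 up by 0.56. Their median of 0.57 gave an adjusted p = 0.000383 (adjusted p = 0.239 with an estimated correlation). Interferon response genes rose in 8 of 19 cases and 11 did not pass (8 adjusted over the list alone), led by Xaf1, Ifit2, Ifit3 and Ifi27l2a with log2 fold changes from 0.73 to 1.04. Camera gave an adjusted p = 4.46e-05, and adjusted p = 0.621 with an estimated correlation. Of 14 p53 targets, Gdf15, Bax, Phlda3, Aen and Trp53 rose, Ccng1 fell and 8 did not pass (6 and 2 adjusted over the list alone). Phlda3, a repressor of Akt signalling, rose from 1.82 ± 0.401 to 9.95 ± 1.85 FPKM. This call (adjusted p = 0.0272; adjusted p = 0.282 with an estimated correlation) was lost in 4 of 29 alternatives, among them those without control replicate 1 (0.0638) and with the immediate early gene score as a covariate (0.0613, range 0.000774 to 0.282). Endoplasmic reticulum chaperones fell in 13 of 17 cases and 4 did not pass (14 adjusted over the list alone), with a median of -0.63. Hspa5, the main chaperone of that compartment, fell from 234 ± 46.4 to 130 ± 7.63 FPKM, Pdia6 by 0.85 and calnexin, Canx, by 0.76 (adjusted p = 1.26e-06 for the list; adjusted p = 0.282 with an estimated correlation). Of 17 NF-kB and cytokine genes, the oncostatin M receptor Osmr rose and 16 did not pass (1 adjusted over the list alone). The call of this list (adjusted p = 0.0357; adjusted p = 0.814 with an estimated correlation) was lost in 11 of 29 alternatives, with adjusted p = 0.641 without control replicate 1 and 0.204 without knockout replicate 1 (range 0.00461 to 0.814).

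Further lists were not called in this comparison. Of 15 heat shock proteins, Hspb6 and Hspb7 rose, Hsph1, Hspe1 and Hspd1 fell and 10 did not pass (2 and 3 adjusted over the list alone; adjusted p = 0.949). Nqo1, Srxn1, Gsr and G6pdx rose, Gstm1 fell and 9 did not pass among 14 NRF2 targets (4 and 1 adjusted over the list alone; adjusted p = 0.586). Of 20 immediate early genes limma called 0 (0 adjusted over the list alone; adjusted p = 0.123), and their mean log2 score was 2.75 in control replicate 1 against 3.72 to 4.73 in the other 9 libraries. In the atrophy and autophagy list, Klf15 fell and 12 of 13 did not pass (1 fell adjusted over the list alone; adjusted p = 0.925). Hypoxia genes held 0 calls among 14 (0 adjusted over the list alone; adjusted p = 0.938), with a median of 0.06, a mean of -0.01 and a downward test. Of 16 clock genes, Bhlhe41 rose and 15 did not pass (0 adjusted over the list alone; adjusted p = 0.949). Cardiac transcription factors were mixed: Tbx20 rose, Mef2a, Tbx5, Klf15 and Hopx fell and 12 of 17 did not pass (4 and 5 adjusted over the list alone). Their median was 0.07, their mean -0.05 and the test pointed down (adjusted p = 0.938). Of 21 cohesin and chromatin architecture genes, the cohesin subunit Stag1, the nuclear lamin Lmna and Hmgb2 rose and 18 did not pass (3 adjusted over the list alone; adjusted p = 0.938). Imprinted genes Plagl1 and Grb10 rose and 14 of 16 did not pass (2 adjusted over the list alone; adjusted p = 0.586). Among 8 clustered protocadherins limma called 0 (0 adjusted over the list alone; median -0.25, adjusted p = 0.197), and none of 39 Hox genes reached the level for testing. Of 74 ribosomal protein genes, Rpl3 rose, Rpl5 fell and 72 did not pass (1 rose and 0 fell adjusted over the list alone; adjusted p = 0.938). None of 5 sex-linked genes passed in limma (0 adjusted over the list alone; adjusted p = 0.925).

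In all, limma called 2362 of 11358 tested genes between CTCF knockout and control, 1203 of them higher and 1159 lower in the knockout, with 198 higher and 157 lower by at least 2-fold. At a mean FPKM of at least 5 the count was 1487 of 6328 tested genes, and 1435 of the 1441 main calls still tested were kept. Without rescaling of the libraries, 1670 genes were called higher and 603 lower, so the balance of directions rests on the scaling. Camera called 16 of 37 tested lists, 9 upward and 7 downward; with an estimated correlation it called 0 (5 at an unadjusted p under 0.05), and fry, which asks whether the genes of a list move one way, called 10. Fry ended the calls of nuclear oxidative phosphorylation genes, mitochondrially encoded genes, the tricarboxylic acid cycle, fibroblast and macrophage markers, the cell cycle and NF-kB genes. Among 117 called results of named genes, 79 kept their call in all alternatives.

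The comparison of TAC with control libraries asks how RNA of the isolated myocytes, with any other cells among them, differs after pressure overload. The natriuretic peptides and matrix genes rose, Fhl1, Xirp2 and Enah rose further than in the knockout, and Ces1d and the potassium channel genes Kcnj3 and Kcnd2 fell. Nppa rose from 43.7 ± 0.323 (SD, n = 3) to 1786 ± 699 FPKM (SD, n = 3), with a log2 fold change of 5.23 (adjusted p = 1.94e-06) and the same limit from Gm13054, which rose by 5.31. Postn, or periostin, a matrix protein of activated fibroblasts (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037, plus strand), rose from 4.55 ± 0.999 to 49.1 ± 5.29 FPKM (log2 fold change 3.18, adjusted p = 1.37e-06). Fhl1, a LIM domain protein of the sarcomere (ENSMUSG00000023092, chromosome X, 56731787 to 56793346, plus strand), rose from 29.7 ± 4.81 to 205 ± 72.0 FPKM (log2 fold change 2.70, adjusted p = 9.05e-05).

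Other genes of the rule with high fold changes were Ankrd1 (3.18), Nppb (3.09), Cilp (2.85), Fam198b (2.52), the stress cytokine Gdf15 (2.50), the endothelin Edn3 (2.49) and the cytoskeletal gene Synpo2l (2.47), all as log2 fold changes. The lowest were Ces1d, Alb, Lgals4, BB218582, Gpr22, Pla2g5, Pfkfb1, Fbp2, Kcnv2 and Il15. Ces1d fell to 12.8 ± 4.63 FPKM (log2 fold change -2.95, adjusted p = 0.000417). Alb lay at 0.0199, 0.0516 and 0 FPKM in the TAC libraries, beside the liver transcripts that were higher in the 3 controls. The orphan receptor Gpr22 fell by 1.70, Lgals4 by 1.89, BB218582 by 1.78, Pla2g5 by 1.68, Pfkfb1 by 1.65, the muscle fructose bisphosphatase Fbp2 and Kcnv2 by 1.59 each and the cytokine Il15 by 1.58. The Il15 call was lost in 9 of 27 alternatives, among them those without control replicate 1 or 2 or TAC replicate 1 or 2 (adjusted p from 0.00431 to 0.145). In the fixed panel, Pln fell by 0.86 (adjusted p = 0.00264). Atp2a2 fell by 0.53 (adjusted p = 0.0493), a call lost in 22 of 28 alternatives, which included 9 of the 10 left-out libraries, all but TAC replicate 2 (adjusted p from 0.0302 to 0.419). Myh7 had a mean of 439 ± 188 FPKM and a log2 fold change of 1.16 (adjusted p = 0.06), Myh6 one of -0.23 (adjusted p = 0.371) and Ryr2 one of -0.14 (adjusted p = 0.786).

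Most stress genes rose under pressure overload, and fewer genes of the glycolysis and hypoxia lists, which were also called upward. These 3 calls were lost with an estimated correlation. Of 13 stress genes, 11 rose, Acta2 fell and 1 did not pass (12 and 1 adjusted over the list alone), with a median log2 fold change of 1.62. Xirp2 rose by 2.16 on the log2 scale to 435 ± 88.1 FPKM and Enah, an actin regulator, from 36.0 ± 2.74 to 113 ± 0.482 FPKM (adjusted p = 3.98e-12 for the list; adjusted p = 0.126 with an estimated correlation). Glycolysis genes rose in 7 of 19 cases and 12 did not pass (10 rose and 1 fell adjusted over the list alone), with Pfkp up by 1.82 and Hk1 by 0.77. Their median of 0.41 gave an adjusted p = 0.00153, and adjusted p = 0.656 with an estimated correlation. Hypoxia genes Ndrg1 and Ero1l rose and 12 of 14 did not pass (3 adjusted over the list alone), with a median of 0.32, an adjusted p = 0.00153 and adjusted p = 0.656 with an estimated correlation. Ion channels and connexins fell in 10 of 21 cases and 9 did not pass (10 fell adjusted over the list alone). Kcnj3 fell by 1.46, Kcnd2 by 1.21 and the calcium channel Cacna1g by 1.16 (adjusted p = 0.000169 for the list; adjusted p = 0.46 with an estimated correlation). Fatty acid oxidation genes fell in 11 of 27 cases and 16 did not pass (11 adjusted over the list alone), with a median of -0.32 and Acaa2 down by 0.95 (adjusted p = 0.000112; adjusted p = 0.66 with an estimated correlation). Of 72 nuclear oxidative phosphorylation genes, Sdha and Cox7a1 fell and 70 did not pass (0 adjusted over the list alone, in limma), with a median of -0.10. This call (adjusted p = 0.0234; adjusted p = 0.867 with an estimated correlation) was lost in 8 of 29 alternatives, among them those without control replicate 2 (0.282), control replicate 3 (0.091), TAC replicate 1 (0.292) or TAC replicate 2 (0.0633), and with no rescaling (0.0655, range 7.83e-07 to 0.867). Of 17 endoplasmic reticulum chaperones, Pdia6, Canx and Herpud1 fell and 14 did not pass (10 fell and 1 rose adjusted over the list alone), with a median of -0.38 (adjusted p = 0.00167; adjusted p = 0.656 with an estimated correlation). Among 74 ribosomal protein genes, Rpl3 rose, Rpl5 fell and 72 did not pass (0 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.000369; adjusted p = 0.738 with an estimated correlation).

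Matrix genes were also higher after TAC, and fibroblast, macrophage, endothelial and erythroid markers were called as lists. All 5 calls were lost with an estimated correlation, and the 4 of the marker lists with fry as well (0.1, 0.0792, 0.204 and 0.175). As in the knockout, the levels of matrix genes cannot be assigned to the myocytes, since markers of other cell types were measured in the same libraries. Of 26 matrix and fibrosis genes, 23 rose and 3 did not pass (25 adjusted over the list alone), with a median of 1.68. Col8a1 rose by 2.14, the matricellular gene Thbs4 by 1.81 and Col1a1 by 1.81 on the log2 scale (adjusted p = 2.69e-27 for the list; adjusted p = 0.102 with an estimated correlation). Fibroblast markers rose in 7 of 15 cases and 8 did not pass (7 adjusted over the list alone; median 0.16, adjusted p = 0.00551). With an estimated correlation this list had adjusted p = 0.687, and it was not called without control replicate 2 (0.147, range 0.00021 to 0.687). Among macrophage markers, the complement gene C1qc, Ctss and Coro1a rose and 14 of 17 did not pass (11 adjusted over the list alone), with a median of 0.49 (adjusted p = 0.000112; adjusted p = 0.656 with an estimated correlation). Endothelial markers were called as a list although limma called 0 of 17 genes (0 adjusted over the list alone), with a median of 0.37. The adjusted p = 0.0123 (adjusted p = 0.687 with an estimated correlation) rose to 0.132 without control replicate 2 (range 0.00211 to 0.687). Erythroid markers were called with 0 of 5 genes passing over all genes and 4 higher adjusted over the list alone, with a median of 1.43. Their mean log2 score was 7.09 in control replicate 1, within the TAC range of 6.81 to 7.57, and 5.15 and 5.33 in control replicates 2 and 3. Their adjusted p = 0.027 (adjusted p = 0.685 with an estimated correlation) rose to 0.113 and 0.0891 without control replicate 2 or 3 and to 0.0671 without TAC replicate 2 (range 0.00042 to 0.685).

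The other lists were not called after TAC. Mature sarcomere genes Mybpc3, Actn2, Myom1 and Myom2 rose, Tnni3 fell and 14 of 19 did not pass (5 and 1 adjusted over the list alone; adjusted p = 0.0805). Calcium handling genes Slc8a1, Casq2 and Srl rose, Atp2a2, Pln, Cacnb2 and Hrc fell and 10 of 17 did not pass (3 and 5 adjusted over the list alone; adjusted p = 0.74). Dsp, Pkp2, Vcl and Xirp2 of the intercalated disc rose and 11 of 15 did not pass (5 adjusted over the list alone; adjusted p = 0.0744). Of 15 cell cycle genes limma called 0 (0 adjusted over the list alone; median 0.28, adjusted p = 0.653). Cdkn1a, Gdf15, Phlda3 and Aen rose among 14 p53 targets, Gadd45a fell and 9 did not pass (6 and 1 adjusted over the list alone; adjusted p = 0.0872). Aldh18a1, Gdf15 and Nupr1 rose, Stc2 fell and 10 of 14 integrated stress response genes did not pass (3 and 1 adjusted over the list alone; adjusted p = 0.0642). Ifi27l2a was the interferon response gene that rose and 18 of 19 did not pass (1 adjusted over the list alone; adjusted p = 0.0618). This list gained a call in 11 of 28 alternatives, among them those without control replicate 2 (0.04), knockout replicate 1 (0.0463), 3 (0.0397) or 4 (0.0233) or TAC replicate 2 (0.0453) or 3 (0.0409) (range 0.00411 to 0.738). Lcn2 and Osmr rose among 17 NF-kB and cytokine genes with 15 not passing (2 adjusted over the list alone; adjusted p = 0.151). Clock genes Nr1d2 and Hlf fell and 14 of 16 did not pass (5 fell adjusted over the list alone; median -0.48, adjusted p = 0.0817). Cardiac transcription factors held a rise of Tbx20, falls of Gata6, Mef2a, Tbx5, Klf15 and Hopx and 11 of 17 that did not pass (2 and 5 adjusted over the list alone; adjusted p = 0.252). Heat shock proteins Hspb6 and Hspb7 rose, Hspe1 and Hspd1 fell and 11 of 15 did not pass (3 and 2 adjusted over the list alone), with a median of -0.13, a mean of -0.05 and an upward test (adjusted p = 0.708). In 3 other lists the median, mean and test differed in sign. Smooth muscle and pericyte markers (Cspg4 and Des rose, Acta2 fell) had a median of -0.10, a mean of 0.03 and an upward test (adjusted p = 0.824). Atrial markers (Nppa rose, Kcnj3 and Tbx5 fell) had a median of -0.65, a mean of 0.35 and a downward test (adjusted p = 0.43). Atrophy and autophagy genes (Foxo3, Klf15 and Cited2 fell) had a median of 0.12, a mean of 0.04 and a downward test (adjusted p = 0.87).

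Against control, limma called 1755 of 11358 genes after TAC, 918 higher and 837 lower, with 204 higher and 111 lower by at least 2-fold. The count was 1153 in a fit of the 2 groups compared and 1129 with Arntl as a covariate. At a mean FPKM of at least 5 it was 1167 of 6328 tested genes, and 1099 of the 1102 main calls still tested were kept. Without rescaling, 1016 were called higher and 513 lower. Camera called 13 of 37 lists, 8 upward and 5 downward; with an estimated correlation it called 0 (3 at an unadjusted p under 0.05), and fry called 8. Besides the marker lists, fry ended the calls of fatty acid oxidation, nuclear oxidative phosphorylation, endoplasmic reticulum chaperones and ribosomal proteins. Among 99 called results of named genes, 62 kept their call in all alternatives that tested them.

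**Figure D2:**
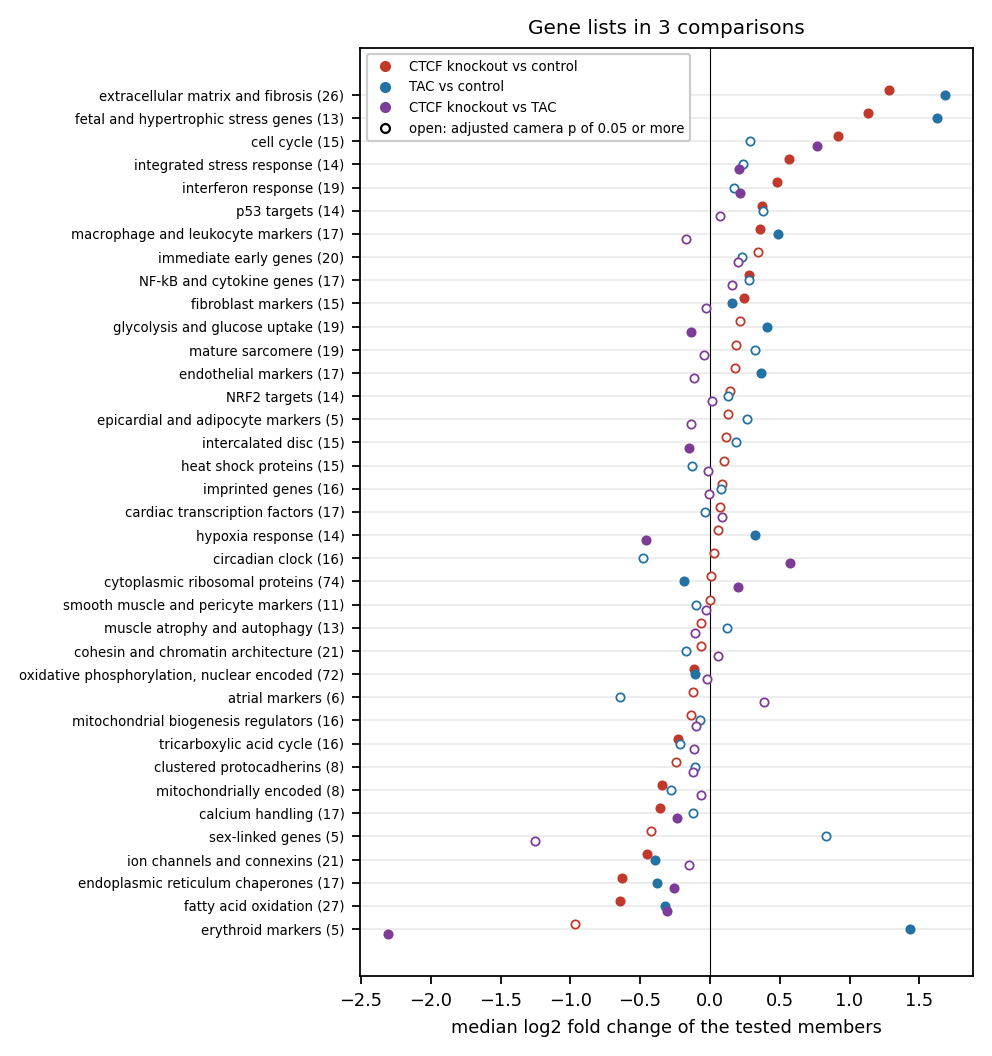
Median log2 fold change of each of the 37 tested gene lists in the 3 comparisons, with the number of tested genes in brackets and open symbols for lists with a camera adjusted p of at least 0.05. Extracellular matrix and fibrosis genes lay highest in both comparisons with control, with a median of 1.29 in CTCF knockout and 1.68 in TAC.

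The direct comparison asks how CTCF knockout and TAC differ. Mnd1, Uchl1, Ndnf and Tlr3 lay higher in the knockout, and Fhl1 and Ptgds lower. Mnd1 lay at 12.5 ± 3.03 FPKM (SD, n = 4) in the knockout and at 0.489 ± 0.112 FPKM (SD, n = 3) after TAC, where the control mean was 0.640 FPKM. Its pseudogene Mnd1-ps, the 1 other gene with a near-identical stretch, reached at most 0.136 FPKM in any library. Its log2 fold change of 3.16 (adjusted p = 1.46e-05) was called in all 28 alternatives, and all 4 knockout libraries lay above all 3 TAC libraries. Uchl1 (ENSMUSG00000029223, chromosome 5, 66676091 to 66687234, plus strand) lay at 42.3 ± 3.93 FPKM in the knockout and 13.1 ± 4.02 FPKM after TAC (log2 fold change 1.66, adjusted p = 0.00208). Ndnf, a secreted protein first found in neurons, and Tlr3, a receptor for double-stranded RNA, were higher in the knockout by 1.48 and 1.31, and Lockd, with the limit given above, by 1.71.

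Fhl1 was lower in the knockout than after TAC by 1.74 on the log2 scale (adjusted p = 0.00396), although it rose against control in both. The adult alpha globins Hba-a1 and Hba-a2 lay at 65.0 ± 43.1 and 77.5 ± 50.9 FPKM in the knockout and at 316 ± 90.3 and 385 ± 113 FPKM after TAC (log2 fold changes -2.42 and -2.46). How reads split between these near-identical copies is uncertain. Control erythroid scores lay in the TAC (7.09) or knockout (5.15, 5.33) range, so no knockout trait was shown. Ptgds, a prostaglandin D synthase (ENSMUSG00000015090, chromosome 2, 25466709 to 25470046, minus strand), and Alas2, the erythroid enzyme of heme synthesis (ENSMUSG00000025270, chromosome X, 150547375 to 150570638, plus strand), were both lower in the knockout by 1.73. The calls of Lockd, Hba-a1, Hba-a2, Ptgds and Alas2 were lost in 13, 9, 9, 6 and 11 of their alternatives, with highest adjusted p of 0.274, 0.151, 0.149, 0.1 and 0.173. For Lockd these held all left-out libraries but control replicate 1 and knockout replicates 3 and 4, for the 2 globins knockout replicates 1, 3 and 4 and TAC replicates 1 and 2, for Ptgds all 3 TAC libraries, and for Alas2 these and knockout replicates 1, 3 and 4. Eef1a1, a translation elongation factor chosen after its values were seen, lay at 331 ± 12.9 FPKM in the knockout, 142 ± 21.7 after TAC and 99.1 ± 17.9 in control, and 19 other genes hold a near-identical sequence, which makes the level uncertain.

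**Figure D3:**
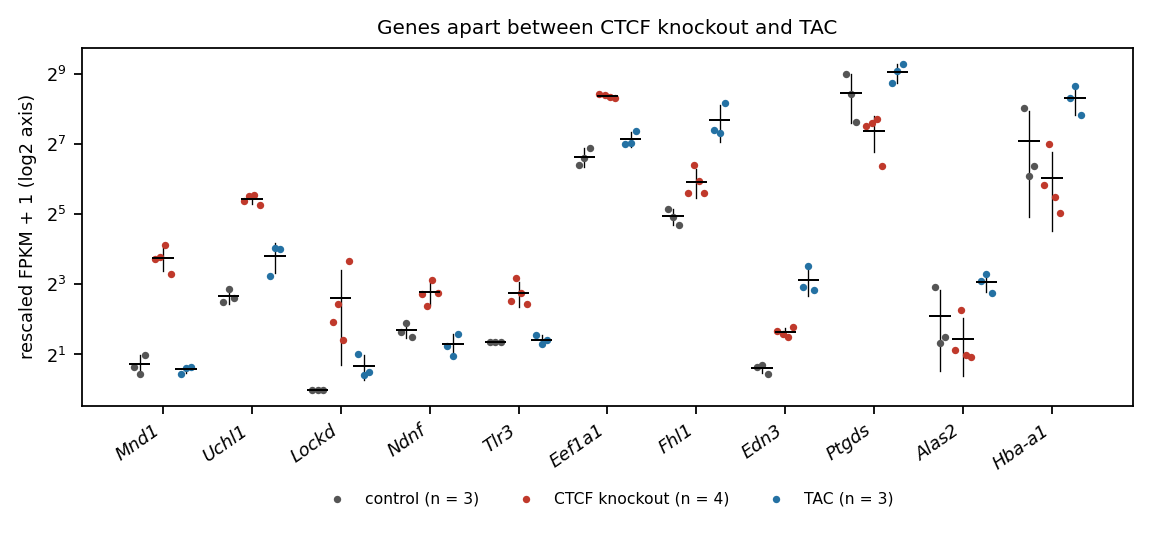
Levels of genes that lay apart between CTCF knockout and TAC libraries, as rescaled FPKM + 1 on a log2 axis, with points for libraries, horizontal lines for group means and vertical bars for the SD. Mnd1 had means of 0.640 FPKM in control, 12.5 FPKM in knockout and 0.489 FPKM in TAC libraries, while Fhl1 had means of 29.7, 59.9 and 205 FPKM.

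By list, camera at its preset correlation called cell cycle, ribosomal protein and clock genes upward in the knockout against TAC, and fatty acid oxidation, erythroid and hypoxia genes downward. Few of their genes passed alone, and all 6 calls were lost with an estimated correlation and all but that of the clock with fry. Of 15 cell cycle genes 0 passed over all genes in limma and 9 were higher adjusted over the list alone, with a median log2 fold change of 0.77, which was 0.378 without knockout replicate 4. Cdk1 and Top2a lay at 4.68 ± 3.89 and 4.70 ± 3.71 FPKM in the knockout and 1.03 ± 0.271 and 1.15 ± 0.442 FPKM after TAC (adjusted p = 5.37e-07 for the list; adjusted p = 0.48 with an estimated correlation). In fatty acid oxidation, Acadl, Cd36, Lpl and Acot2 were lower and 23 of 27 did not pass (9 adjusted over the list alone), with a median of -0.31. Cd36, the fatty acid carrier of the myocyte membrane, lay at 388 ± 36.1 FPKM in the knockout and 610 ± 90.3 after TAC (adjusted p = 2.3e-07 for the list; adjusted p = 0.48 with an estimated correlation). The erythroid genes Hba-a1, Hba-a2 and Alas2 were lower and 2 of 5 did not pass (5 adjusted over the list alone), with a median of -2.31 (adjusted p = 1.01e-05; adjusted p = 0.48 with an estimated correlation). Hypoxia genes Hk2 and Ero1l were lower and 12 of 14 did not pass (8 adjusted over the list alone), with a median of -0.45 (adjusted p = 1.01e-05; adjusted p = 0.48 with an estimated correlation). None of 74 ribosomal protein genes passed in limma (0 adjusted over the list alone), and their median was 0.20 (adjusted p = 2.3e-07; adjusted p = 0.767 with an estimated correlation).

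Calcium handling genes Cacna2d1 and S100a1 were lower in the knockout and 15 of 17 did not pass (7 adjusted over the list alone), with a median of -0.23 (adjusted p = 0.000408; adjusted p = 0.132 with an estimated correlation). Stress genes Xirp2, Fhl1, Enah and Flnc were lower, Uchl1 was higher and 8 of 13 did not pass (7 and 2 adjusted over the list alone), with a median of -0.69. For this list (adjusted p = 0.0012; adjusted p = 0.48 with an estimated correlation), Arntl as a covariate ended the call (0.0707, range 7.93e-05 to 0.48). Matrix genes Tgfb3 and Comp were higher, Col4a2 and Thbs4 lower and 22 of 26 did not pass (2 and 6 adjusted over the list alone), with a median of -0.29. The call (adjusted p = 0.00443; adjusted p = 0.663 with an estimated correlation) was lost without knockout replicate 3 (0.0897), at a mean FPKM of at least 5 (0.0815) and with Arntl as a covariate (0.466, range 0.000514 to 0.663). Ddit3 was higher among 14 integrated stress response genes and 13 did not pass (3 adjusted over the list alone; median 0.21, adjusted p = 0.00443; adjusted p = 0.48 with an estimated correlation), and the call was lost at a mean FPKM of at least 5 (0.0967, range 0.000108 to 0.48). None of 17 endoplasmic reticulum chaperones passed in limma (0 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.0012; adjusted p = 0.526 with an estimated correlation). This call was lost without TAC replicate 2 (0.0544) and with Arntl as a covariate (0.589, range 5.57e-05 to 0.589). Of 19 interferon response genes 0 passed in limma over all genes and 2 were higher adjusted over the list alone, with a median of 0.21 (adjusted p = 0.0012; adjusted p = 0.663 with an estimated correlation), and the call was lost without knockout replicate 4 (0.0553) and with Arntl as a covariate (0.0608, range 1.74e-06 to 0.663). In the intercalated disc list Xirp2 was lower and 14 of 15 did not pass (3 lower and 1 higher adjusted over the list alone; median -0.15). Its call (adjusted p = 0.0323, and 0.48 with an estimated correlation) was lost in 8 of 29 alternatives. The adjusted p rose to 0.07 and 0.0739 without knockout replicate 3 or TAC replicate 3, to 0.0702 with no rescaling and to 0.292 with quantile normalization (range 0.00261 to 0.48). Hk2 was lower among 19 glycolysis genes and 18 did not pass (1 adjusted over the list alone; median -0.13). That call (adjusted p = 0.0483; adjusted p = 0.767 with an estimated correlation) was lost in 15 of 29 alternatives, including those without control replicate 2 (0.054) or 3 (0.0511), knockout replicate 4 (0.391) or TAC replicate 2 (0.17) or 3 (0.126), with no rescaling (0.0737) and with quantile normalization (0.844, range 0.00619 to 0.844).

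The circadian clock list was called here and not in the comparisons with control, although against control the TAC call was gained without control replicate 3 (adjusted p = 0.0121), with no rescaling (0.0281) and with fry (0.0375, range 0.0121 to 0.656). Hlf, an output transcription factor of the clock, was higher in the knockout and 15 of 16 did not pass over all genes (8 higher and 2 lower adjusted over the list alone), with a median of 0.58. Arntl, the activator at the core of the clock, lay at 0.370, 0.566, 0.755 and 0.509 FPKM in the knockouts and between 3.14 and 5.05 FPKM after TAC, and at 0.549, 0.296 and 7.59 FPKM in control replicates 1 to 3. Per3 and Dbp lay at 5.11 ± 0.431 and 29.8 ± 3.29 FPKM in the knockout and 1.49 ± 0.109 and 7.63 ± 3.08 FPKM after TAC. The list had an adjusted p = 0.00443 (adjusted p = 0.237 with an estimated correlation), and the call was lost at a mean FPKM of at least 5 (0.0967) and with Arntl as a covariate (0.255, range 0.000265 to 0.255).

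**Figure D4:**
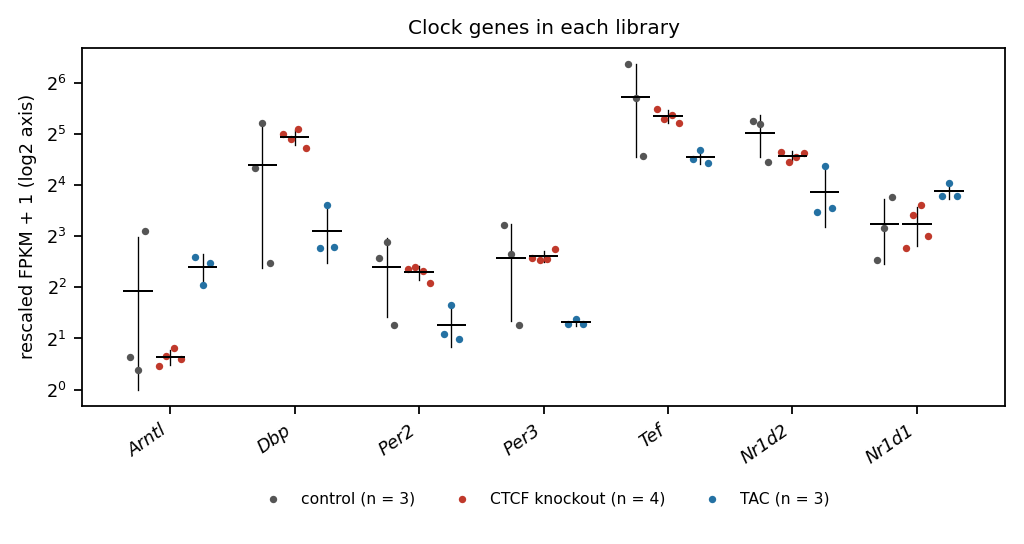
Levels of 7 circadian clock genes in each library, as rescaled FPKM + 1 on a log2 axis, with points for libraries, horizontal lines for group means and vertical bars for the SD. Arntl lay at 0.549, 0.296 and 7.59 FPKM in control replicates 1 to 3, from 0.370 to 0.755 FPKM in knockout and from 3.14 to 5.05 FPKM in TAC libraries.

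Of the lists not called between knockout and TAC, ion channels held called genes in both directions, with Kcnj5, Kcnj11 and Kcnh2 among those higher, Kcnq1 and Kcnk3 among those lower and 13 of 21 that did not pass (adjusted p = 0.711). Phlda3 and Gadd45a were the p53 targets that were higher (2 adjusted over the list alone; adjusted p = 0.336), Stag1 the cohesin gene (1 adjusted over the list alone; adjusted p = 0.237) and Myom1 the sarcomere gene that was lower (1 adjusted over the list alone; adjusted p = 0.5). Hspb6 and Hspb7 were lower among 15 heat shock proteins (3 adjusted over the list alone), with a median of -0.02, a mean of 0.06 and a downward test (adjusted p = 0.394). NRF2 targets had a median of 0.02, a mean of -0.02 and a downward test (adjusted p = 0.758), and nuclear oxidative phosphorylation genes a median of -0.02, a mean of 0.00 and an upward test (adjusted p = 0.883). Fibroblast, endothelial, macrophage and smooth muscle markers had medians of -0.03, -0.12, -0.17 and -0.03 and no call (adjusted p = 0.773, 0.151, 0.14 and 0.388).

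Between CTCF knockout and TAC, limma called 372 of 11358 genes, 179 higher and 193 lower in the knockout, with 24 higher and 19 lower by at least 2-fold. Without rescaling, 212 were higher and 120 lower. The count was 195 with no filter on the mean, 200 with a block by replicate number, 233 with a sex term and 21 with Arntl as a covariate. It was 152, 133, 156, 135 and 189 without knockout replicate 1, knockout replicate 3, TAC replicate 1, TAC replicate 2 and TAC replicate 3. Camera called 14 of 37 lists, 5 upward and 9 downward; with an estimated correlation it called 0 (3 at an unadjusted p under 0.05), fry ended all calls but those of calcium handling and the clock, and the count was 7 at a mean FPKM of at least 5 and 9 with Arntl as a covariate. Of 36 called results of named genes in this comparison, 1 (Mnd1) kept its call in all alternatives.

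A comparison of both effects asks how far the response to the CTCF knockout matches that to pressure overload. Nppa, Ankrd1, Postn, Cilp, Fam198b and Gdf15 rose and Ces1d, Pfkfb1, Kcnv2, Pla2g5 and Kcnj3 fell in both. Both comparisons called 1162 genes, of which 599 rose in both, 562 fell in both and 1 went opposite ways. That gene was Wrnip1, a protein of stalled replication forks (ENSMUSG00000021400, chromosome 13, 32802038 to 32822609, plus strand), chosen after its values were seen. It rose to 9.52 ± 1.49 FPKM in the knockout and fell to 3.72 ± 0.360 FPKM after TAC, from 6.35 ± 0.414 FPKM in control. The log2 fold changes were 0.51 (adjusted p = 0.0128) and -0.64 (adjusted p = 0.00739), and 1.15 between knockout and TAC (adjusted p = 0.00208). Independent lists of these sizes would share 97.2 risen and 85.4 fallen genes, numbers that leave the shared controls out of account. Simulated unchanged groups against the same controls shared 0 to 1, but they called almost no genes, so this value does not give the part of the overlap that comes from the controls. The overlap was 771 at a mean FPKM of at least 5, where only 6328 genes were tested, and fell to 706 with Arntl as a covariate. Among 2955 genes called in either comparison, 2799 had the same sign in both. The knockout alone was called for 1200 genes, 168 of them also called between knockout and TAC, and TAC alone for 593 genes, 93 of them also called between the 2. For the rest of these genes a difference between the effects was not shown.

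Across the 11358 genes, the 2 sets of log2 fold changes had a Pearson r of 0.780 and a Spearman rho of 0.733. Simulated unchanged groups with the same controls gave means of 0.534 and 0.508 with independent noise per gene (Pearson r from 0.466 to 0.572). With whole residual columns drawn, which keeps genes moving together, Pearson r of unchanged groups ranged from -0.488 to 0.971, a range that holds the observed value. The covariance was 0.133 against a simulated 0.0149 with independent noise, a difference of 0.118, and against -0.01 to 0.111 with residual columns drawn. With 3 control libraries no split into parts of at least 2 was possible, so part of the excess may come from the shared controls. The correlation was 0.693 with no length filter and 0.669 with Arntl as a covariate.

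**Figure D5:**
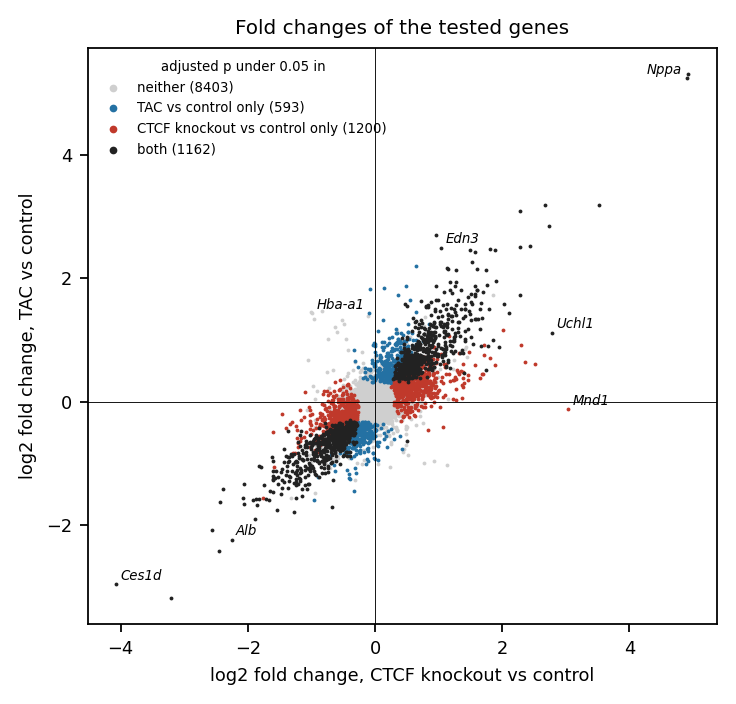
Log2 fold changes of the 11358 tested genes in CTCF knockout vs control and in TAC vs control, with a point per gene and colours for genes called in both comparisons (1162), in the knockout alone (1200), in TAC alone (593) or in neither (8403). Pearson r was 0.780, and unchanged groups with the same controls gave r from 0.466 to 0.572 with independent noise and from -0.488 to 0.971 with residual columns drawn.

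Because CTCF shapes chromatin domains, a further comparison asks whether adjacent genes moved together. Over 10088 pairs of neighbouring genes that do not overlap, log2 fold changes of neighbours correlated with Spearman rho 0.126 in the knockout and 0.108 after TAC. In both, the one-sided permutation p = 0.000999 was the smallest that 1000 shuffles of gene order can give, and the highest shuffled rho was 0.0355 and 0.0385. Regroupings of the same libraries had rho of at least 0.0407 and 0.0408, above all shuffles, so this p holds for any grouping and says nothing of a response to the CTCF knockout or TAC. Pairs within 50 kb had rho 0.227 and 0.178. Between knockout and TAC, neighbours correlated with rho 0.0724, and 4 of 35 splits of these libraries, the real one included, gave as high a value. This relation is across genes, which are not independent replicates.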

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

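The tests of cell cycle genes, of clock genes, of liver RNA as a source of fallen genes and of neighbours in splits of CTCF knockout and TAC were chosen after the result was seen, while the other splits of the libraries and the test of liver markers not looked at before were not. In groups of 4 libraries, which are the knockouts alone, a library was marked when it lay far from the other 3 for its group range, a rule that chance meets in about 1 in 20 groups. It was met in 9 of 78 groups. Knockout replicate 4 was the library in 6 of them. It held Ube2c at 11.7 FPKM (others 2.95 to 3.59), Alb at 0.0219 FPKM (others 0), Ptgds at 81.6 FPKM (others 183 to 208), the fatty acid oxidation score at 6.62 (others 6.92 to 6.98) and the cell cycle score at 2.72 (others 1.61 to 1.73). Its sex-linked score was 2.96 (others 0.572 to 0.752), and this is the 1 male mouse among the knockouts. Knockout replicate 2 had Alas2 at 3.83 FPKM (others 0.888 to 1.17) and an endoplasmic reticulum chaperone score of 3.93 (others 3.96). Knockout replicate 1 had an NRF2 target score of 4.20 (others 4.06 to 4.08).

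Genes with transcripts under 300 nt, which the comparisons leave out, held calls as well. Of 401 such genes, 23 differed between CTCF knockout and control (15 higher, 8 lower) and 20 between TAC and control (15 higher, 5 lower). FPKM of short transcripts is unstable, and no explanation was tested.

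Other splits of the same libraries into groups of the same sizes show how often another division gave as large a value. For genes changed between CTCF knockout and control, 1 of 35 splits, the real one, gave as many (2362, highest other 1), and for CTCF knockout and TAC 1 of 35 (372, highest other 2). This is the smallest share that 35 splits can give. Mixed splits also hold the group difference within their groups, and the splits cannot separate a group effect from a separate handling of the groups. The 3 control and 3 TAC libraries make 10 splits, too few for a share under 0.05, for genes (1 of 10; real 1755, highest other 1), lists (9 of 10; real 13, highest other 21) and neighbours (2 of 10; real 0.108, highest other 0.108). For the number of lists, chance is not excluded between CTCF knockout and control, where 10 of 35 splits gave as many (real 16, highest other 19), or between CTCF knockout and TAC, where 13 of 35 did (real 14, highest other 19). The counts of called lists therefore carry no evidence of a group effect by themselves. For the rho of neighbouring genes in CTCF knockout, 1 of 35 splits, the real one, gave as high a value (real 0.126, highest other 0.121), but this margin is smaller than the change from leaving out 1 library (0.115 without control replicate 3), so it is weak evidence. For that rho between CTCF knockout and TAC chance is not excluded, since 4 of 35 splits gave as high a value (real 0.0724, highest other 0.0790). For genes called in both comparisons, 1 of 100 regroupings gave as many as the real 1161, and the highest other, 1095, kept the 3 controls together and put knockout replicate 4 with the 3 TAC libraries. For the correlation of fold changes chance is not excluded, since 6 of 100 regroupings gave as high a value (real 0.780, highest other 0.840).

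Cell cycle genes lay higher in CTCF knockout than in TAC libraries, with a median log2 fold change of 0.767. A larger share of cells other than myocytes would raise their markers alike, but 60 markers of 4 other cell types had a median of -0.0954 and a 90th percentile of 0.103, which argues against it. Knockout replicate 4 alone is not the whole cause either: without it the median difference was 0.378, 13 of 15 genes were positive, and the lowest score of the other knockouts, 1.61, lay above the highest of TAC and control, 1.43. A dividing subset of another cell type stays open, as does a change in the myocytes, and the difference between cell cycle and marker scores (0.812) had an exact permutation p = 0.0571. The rise in the knockout may thus be biological as a hypothesis, and it was not tested in other data.

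Clock genes lay apart between CTCF knockout and TAC libraries, with control replicate 3 on the side of TAC. If the hour of collection was the source, control replicate 3 would lie nearer TAC and control replicates 1 and 2 nearer the knockout over the whole clock. This arrangement held for 10 of 16 clock genes, against 6.02% of all tested genes and at most 6 in 10000 random lists of similar level (0% had as many), but it was first seen on these genes, so the count restates the observation and does not support this source. A mislabelled TAC library is argued against by the stress gene score of control replicate 3, 6.22, beside 5.78 and 6.04 in the other controls and 7.67 to 8.22 in TAC. The hour of collection, which the labels do not give, cannot be told apart from an effect of the CTCF knockout or pressure overload on the clock, and both stay open.

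Liver transcripts such as Alb lay at low levels in the 3 control libraries. RNA of liver cells in those libraries may be the source: of 37 liver markers not looked at before, 18 lay higher in all 3 controls than in all 7 other libraries, against 5.47% of all genes and a chance of 1 in 120. Alb reached 4.15 FPKM in the controls, Trf reached 8.32 FPKM there but lay higher in 6 of the 7 other libraries and so did not follow the pattern, and of 57 markers 3 reached 1 FPKM in a knockout or TAC library (Trf, Apoa2 and Ahsg), while the isolation of myocytes would be expected to remove liver cells. The same RNA is argued against as the source for 288 of the 562 genes that fell in both comparisons (51.2%), since each fell by more FPKM than Alb in each, and for the other 274 this source cannot be told apart from a fall in the myocytes, because they fell by less FPKM than Alb in at least 1 comparison. A separate handling of the controls is confounded with the group, since the labels give no dates, and no biological explanation was tested.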

How the results depend on the processing

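The alternatives that kept the genes listed at 0, used the Arntl level or the immediate early gene score as a covariate, or took protein-coding genes alone were chosen after the result was seen. Among 470 results of named genes (252 called), 12978 alternative values gave 11987 counted as the same, 759 that lost a call, 232 that gained one and 0 that reversed. A result without a call counted as the same when it stayed without one, whatever its direction, and many named genes were chosen by their values here. Over all genes, the block by replicate number kept 1699 of 2362 calls in CTCF knockout against control. The Arntl covariate kept 19 of 372 between CTCF knockout and TAC. For lists, 2958 of 3186 values were the same, 143 lost a call, 85 gained one and 0 reversed. Robust moderation was not run for lists.

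A mean FPKM of at least 5 gave 1487 genes for CTCF knockout against control, 1167 for TAC against control, 771 called in both and 7 lists between CTCF knockout and TAC; fewer genes were tested. With no filter on the mean, 195 genes were called between CTCF knockout and TAC. With no length filter the correlation of fold changes was 0.693. A fit of the 2 groups compared gave 1153 genes for TAC against control, from fewer libraries. A term for sex gave 233 genes between CTCF knockout and TAC. With the Arntl level as covariate, 1129 genes were called for TAC against control, 21 between CTCF knockout and TAC and 706 in both, the correlation was 0.669, and 9 lists were called between CTCF knockout and TAC. Arntl lay apart between these 2 groups, so the covariate takes up part of the difference itself. Except for this overlap of Arntl with the groups and the smaller numbers tested, the cause was not tested.

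A camera test with an estimated correlation called 0, 0 and 0 lists in CTCF knockout against control, TAC against control and CTCF knockout against TAC (5, 3 and 3 at an unadjusted p under 0.05), while fry called 10, 8 and 2. The lowest adjusted p with an estimated correlation were 0.173, 0.102 and 0.132. Without this alternative, 6, 5 and 1 of the called lists kept their call in all others that tested them. The list calls thus depend on the form of the camera test. A higher correlation was not the reason for every loss. Calcium handling and the clock had estimated correlations of -0.0237 and 0.00499, below the preset 0.01, and lost their calls too. What else in this alternative ended those calls was not tested. Lists without a call gained one in some alternatives, most often the interferon response after TAC (11 of 28), glycolysis and mitochondrial biogenesis in CTCF knockout against control and the tricarboxylic acid cycle after TAC (6 of 29 each) and the integrated stress response after TAC (5 of 29).

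A block by replicate number gave 200 genes between CTCF knockout and TAC, and 1816 and 1544 against control. It ended the calls of the oxidative phosphorylation (0.554), fibroblast, macrophage and NF-kB (0.0582 each) and p53 lists (0.0526) in CTCF knockout against control and of glycolysis between CTCF knockout and TAC (0.306). Residuals of same-numbered libraries had r from -0.359 to 0.327, over 0.1 in 4 of 9 pairs. These r were not set against those of differently numbered libraries, so whether the numbers pair the mice stays unknown.

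With each library left out in turn, genes ranged from 1689 to 2323 for CTCF knockout against control, from 1239 to 1656 for TAC against control and from 133 to 443 between CTCF knockout and TAC. The last count was 152 and 133 without knockout replicate 1 or 3, and 156, 135 and 189 without TAC replicate 1, 2 or 3. Genes called in both ranged from 854 to 1002, the correlation from 0.744 to 0.803, the Ctcf log2 fold change from -1.12 to -0.92, lists from 13 to 17, 10 to 16 and 13 to 17, and neighbour rho from 0.115 to 0.129 in CTCF knockout and from 0.0975 to 0.112 after TAC. No read counts were analysed here, so what depth limits is unknown.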

Other observations

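All values here were chosen after the data were examined. Loci listed at 0 in some libraries and high in others were set apart from the comparisons. Ttn, which encodes titin, was listed at 0 in control replicate 1, knockout replicate 4 and TAC replicates 1 and 3 and lay between 489 and 911 FPKM in the other 6 libraries. The mitochondrial gene mt-Co3 was listed at 21868 FPKM in knockout replicate 2 and at 0 in the other 9 libraries, and mt-Atp6 at 11657 FPKM and 0 in the same way. Rn7s1, an RNA of the signal recognition particle, was listed at 0 in TAC replicate 3 and lay between 48293 and 102730 FPKM in the other 9 libraries.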
